A study of Homo sapiens with 4 samples.

How the data were processed

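RNA from the U118-MG line, an established human glioma line grown in DMEM with 10% fetal bovine serum at 37 °C under 5% CO2, was sequenced in 4 libraries. The NC group (2 libraries) had received the negative control lentiviral vector and the SPNS2 group (2 libraries) the vector that carries SPNS2. Per the labels' protocols, RNA was taken up in Trizol and 1 µg of total RNA went into each library. Nothing in the labels says that the 2 libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

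The values deposited by the authors are raw counts per Ensembl gene, whole numbers that were not normalized, with 1 column per library. Trim Galore 0.6.9, HISAT2 2.2.1, featureCounts 0.3 and the build hg38 are named in the submitters' processing notes, with no order or settings. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies therefore cannot be assigned with certainty, and reads of the introduced SPNS2 and of the cells' own gene are counted together. The table held 61806 genes and 1 further row of annotation text without counts, which was left out. Total counts were 31513400 and 32992150 in the NC libraries and 31353373 and 34125159 in the SPNS2 libraries. Intervals and floors given for low counts cover counting error only.

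Gene positions, lengths and GC content came from GENCODE release 29 on GRCh38, the same assembly as hg38, by Ensembl identifier, and 17382 of the tested genes had a match. Start and end positions are 1-based.

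Genes were kept by filterByExpr on the group (minimum count 10, minimum total 15), which left 17853. Counts were scaled by TMM, and SPNS2 was compared with NC by the two-sided quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest) with the group as the only term. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p under 0.05. Unless another tool is named, each adjusted p of a gene comes from this edgeR test. The standard error of a log2 fold change is the fitted value divided by the square root of its F statistic. Levels are TMM-scaled CPM (counts scaled to a common library size), given as mean ± SD with n = 2 libraries per group. A fold against a group with no counts was taken against a floor of 3 counts over the group and is a lower bound, and a ratio against 1 to 3 counts is given with its exact counting interval.

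Before the data were examined, 50 gene lists were written down, of which 47 had at least 5 tested genes. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, and adjusted over the lists. These p-values compare the members with the other genes. They rest on the spread across genes, which are not independent replicates, under that assumed correlation. SPNS2 was left out of each list. The result of 1 of the 47 lists is not reported here, but the list stayed in the adjustment. The named genes were also fixed by a rule: SPNS2, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM whose groups did not overlap, the S1P kinases, lyase and receptors whatever their p, up to 4 members with the smallest p of each called list and up to 3 of each other list discussed.

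The gene test was tested on simulated counts with the means of the NC libraries and the library sizes of these samples. Each tested gene had the trended dispersion of the fit, with no gene spread more than the trend, and only the genes below were changed. The rates describe that setting, not genes with a larger spread in these samples. In the simulated comparison of SPNS2 with NC over 17629 genes, the test called 14% of 50 genes changed 1.5-fold, 50% of those changed 2-fold, 66% of those changed 4-fold and 88% of those changed 8-fold, and 5 of its 114 calls were unchanged genes. In a second simulation over 17666 genes, cholesterol synthesis, shifted by 0.5 on the log2 scale, was the 1 list called of 46. An arm shifted by 0.4 had a median of 0.38. Genes were drawn independently in the simulations, so they cannot show how often correlated members give false list calls. In these samples the estimated correlation of the cholesterol synthesis list was 0.29.

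The alternatives were DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, RLE and upper-quartile factors, library totals without factors, no low-count filter, a minimum mean of 1 CPM, a replicate block, each library left out in turn, and glmTreat against a fold of 1.2. For lists they were camera with an estimated correlation and the rotation test fry. A fit with the median of each chromosome arm removed from the SPNS2 libraries was added after the data were seen, with arms divided at approximate centromere positions. Overlaps between genes were found with GenomicRanges 1.54.1. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Levels of XIST and Y-linked genes are not reported.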

Results

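Gene expression was measured by RNA sequencing in U118-MG glioma cells that carried either the control vector (NC, 2 libraries) or a vector for SPNS2 (2 libraries), a membrane transporter that exports the signalling lipid sphingosine 1-phosphate (S1P). The comparison asks how the transcriptome differs between the SPNS2 and the control cells. Between 31353373 and 34125159 reads per library were assigned to genes, and 23501 to 25096 genes had at least 1 count. The 10 most abundant genes took 5.77% to 6.18% of the counts. Across the tested genes, Spearman correlations were 0.983 and 0.984 within the groups and 0.947 to 0.949 between them, and the first principal component held 71.7% of the variance. The libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 30.5 in NC and 37.3 in SPNS2. This does not tell technical from biological spread, and the libraries were counted as samples because the labels number them as replicates.

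SPNS2 itself (ENSG00000183018, chromosome 17, 4498838 to 4539035 on hg38) was read 42 and 47 times in the NC libraries and 7381 and 8224 times in the SPNS2 libraries. Its level was 1.35 ± 0.061 CPM in NC and 243 ± 4.75 CPM in SPNS2 (SD, n = 2), a log2 fold change of 7.48 (SE 0.086, edgeR adjusted p = 0.00028). Transcripts of the vector and of the cells' own gene were not separated in these counts.

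Genes of many kinds differed between the groups: of 17853 genes tested, 2161 rose and 2010 fell in the SPNS2 cells, 4171 in all by the edgeR quasi-likelihood test. THBS1, which encodes the matrix glycoprotein thrombospondin 1, rose 15.8-fold, from 124 ± 3.86 to 1963 ± 12.3 CPM, and MMP1, an interstitial collagenase, rose 4.74-fold to 4849 ± 62.8 CPM. IGFBP3, a binding protein of insulin-like growth factors, fell 64.5-fold from 2697 ± 95.1 to 41.8 ± 4.14 CPM. PDGFRA, a receptor of platelet-derived growth factor, fell 2.79-fold from 1166 ± 54.2 to 419 ± 8.09 CPM. At least a 2-fold change was met by 775 of the genes that rose and 992 of those that fell. The 2 groups did not overlap at any called gene, which a call with 2 libraries per group nearly requires, so it is not separate support. They did not overlap at 66% of the tested genes, where chance gives 33.3%. Leaving out a library lowered the number of called genes to 1712 (without NC replicate 1), 1759 (without NC replicate 2), 2144 (without SPNS2 replicate 1) and 1965 (without SPNS2 replicate 2). Fold changes also shifted along chromosome arms, from a median of -0.39 on 11q to 0.43 on 5q, and 3278 genes were called with the arm medians removed, an alternative chosen after seeing the data.

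**Figure D1:**
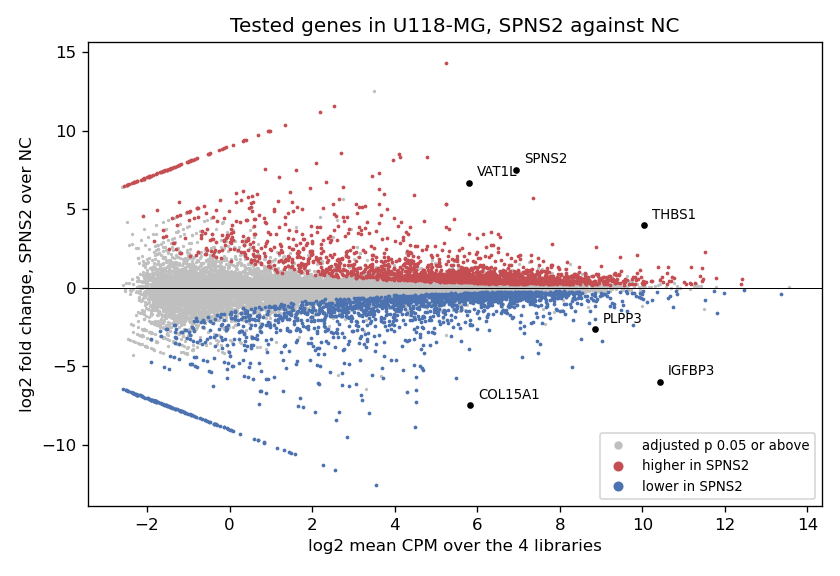
Each point is a tested gene, with the log2 mean CPM over the 4 libraries on the x axis and the log2 fold change of SPNS2 over NC on the y axis. Genes called higher (2161, red) and lower (2010, blue) lie on both sides of 0, SPNS2 lies at 7.48, and the diagonal edges at low levels hold genes with no counts in a group, whose fitted folds are not measured sizes.

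Among the genes with the highest fold changes, RNF17 (a tudor-domain protein of germ cells) had no counts in NC and 11.6 ± 0.157 CPM in SPNS2, at least 254-fold higher. The X-linked SPANX genes, known as cancer-testis antigens, were represented by SPANXA1, SPANXD, SPANXA2 and SPANXC. These are near-identical copies whose reads could be divided between them, so the sum of the 11 family members in the table is given: 6.95 ± 0.214 CPM in NC and 484 ± 10.3 CPM in SPNS2, 69.6-fold higher. LDOC1, on the same part of the X chromosome (141175745 to 141177125), rose from 0.151 ± 0.081 to 21.6 ± 2.29 CPM with a log2 fold change of 7.12 (SE 0.34, edgeR adjusted p = 0.0016). With a library left out, LDOC1 ranged from 6.67 to 7.79. NLGN4X, a neuroligin of synaptic adhesion, rose to 24.7 ± 1.42 CPM, AVPR1A, a vasopressin receptor, to 9.94 ± 1.01 CPM, ADGRF5, an adhesion G protein-coupled receptor, to 13.3 ± 0.181 CPM and VAT1L to 110 ± 2.97 CPM, from 0.154 ± 0.0914, 0.0892 ± 0.126, 0.152 ± 0.0379 and 1.07 ± 0.338 CPM in NC. The log2 fold changes of NLGN4X and AVPR1A, with 0 to 7 counts in each NC library, ranged from 6.79 to 8.05 and from 5.77 to 11.3 when a library was left out. PEDS1-UBE2V1, a read-through gene, had no counts in NC and 76.4 ± 70.3 CPM in SPNS2, but it overlaps PEDS1 and UBE2V1, and the sum of the 3 was 210 ± 0.5 CPM in NC and 233 ± 13.6 CPM in SPNS2. Its call is uncertain for that reason. Apart from that, the call was lost with limma-voom (adjusted p = 0.284) and a robust edgeR fit (adjusted p = 0.0762). The fitted log2 fold changes stayed large, at 11.9 and 14.3 against 14.3 in the main fit. They were 14.3 without NC replicate 1 and 14.3 without NC replicate 2. The SPNS2 libraries themselves differed, at 26.6 and 126 CPM.

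The lowest fold changes included genes that were abundant in the control cells. COL15A1, a basement membrane collagen, fell from 112 ± 6.23 to 0.611 ± 0.45 CPM, a log2 fold change of -7.49 (SE 0.43, edgeR adjusted p = 0.0023). With a library left out, COL15A1 ranged from -8.56 (without SPNS2 replicate 2) to -6.89 (without SPNS2 replicate 1). FER1L6 fell from 44.8 ± 1.07 to 0.0949 ± 0.0495 CPM, PTCHD1 from 45.4 ± 2.31 to 0.29 ± 0.226 CPM, HS6ST3, a heparan sulfate sulfotransferase, from 45.2 ± 1.7 to 0.507 ± 0.293 CPM, and MAP7, a microtubule-associated protein, from 39.2 ± 0.724 to 0.394 ± 0.133 CPM. SCARA5, a scavenger receptor for ferritin, was at 23.2 ± 1.76 CPM in NC and had no counts in SPNS2, at least 496-fold lower. The alcohol dehydrogenases ADH7 and ADH1B lie near each other on chromosome 4 (99412261 to 99435737 and 99304964 to 99352760). ADH7 was at 11.7 ± 0.724 CPM in NC and without counts in SPNS2, at least 250-fold lower, and ADH1B fell from 20.6 ± 0.77 to 0.0749 ± 0.106 CPM. The endothelin receptor EDNRB fell from 18.4 ± 1.84 to 0.13 ± 0.184 CPM and the chemokine receptor ACKR3 from 18 ± 1.02 to 0.152 ± 0.124 CPM. With a library left out, the log2 fold changes ranged from -12.4 to -7.05 for ADH1B, -12.2 to -6.12 for EDNRB, -9.44 to -8.39 for FER1L6, -8.4 to -6.63 for PTCHD1, -8.03 to -6.19 for ACKR3 and -7.2 to -5.97 for HS6ST3. The zinc finger genes ZNF677 and ZNF423 had 1 to 3 counts over the SPNS2 libraries, with ratios of NC to SPNS2 of 384 (95% counting interval 106 to 3174) and 267 (90.9 to 1295). With a library left out, their log2 fold changes ranged from -11.6 to -7.44 (ZNF677) and from -11.7 to -6.94 (ZNF423).

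The genes of S1P metabolism and signalling moved in both directions. SPHK1, a kinase that makes S1P, rose 4.56-fold, from 19.9 ± 0.673 to 90.8 ± 6.89 CPM (edgeR adjusted p = 0.0013). PLPP3, a phosphatase that breaks down extracellular S1P and related lipids, fell 6.24-fold from 790 ± 32.6 to 127 ± 3.48 CPM (edgeR adjusted p = 0.00059), and ABCG2, an export pump, rose 4.93-fold from 3.28 ± 0.306 to 16.2 ± 0.105 CPM. Of the S1P receptors, S1PR3 rose from 54.9 ± 0.0735 to 96 ± 7.69 CPM (edgeR adjusted p = 0.007) and S1PR2 fell from 28.3 ± 1.27 to 16 ± 0.611 CPM (edgeR adjusted p = 0.0123). S1PR1 (2.27 ± 0.315 and 3.04 ± 1.03 CPM, adjusted p = 0.43) and S1PR5 (4.48 ± 0.24 and 3.99 ± 0.381 CPM, adjusted p = 0.59) did not pass the test, and S1PR4 had no counts in any library. SPHK2 was at 48.5 ± 2.04 CPM in NC and 38.6 ± 1.64 CPM in SPNS2 (adjusted p = 0.062), and the S1P lyase SGPL1 at 38 ± 2.36 and 37.2 ± 2.19 CPM (adjusted p = 0.872). In the S1P pathway list, 4 of 19 tested members rose, 5 fell and 10 were not called, with 4 higher and 6 lower when adjusted over the list alone, and camera did not call the list (adjusted p = 0.709). Its median was -0.11 and its mean 0.05 on the log2 scale, while camera gave the direction lower. The call of S1PR2 was lost without NC replicate 2 (adjusted p = 0.0647) and without SPNS2 replicate 1 (adjusted p = 0.0552), and SPHK2 was called by DESeq2 (adjusted p = 0.0432), with upper-quartile factors (0.0468), with library totals only (0.0428), with a minimum mean of 1 CPM (0.0496) and with arm medians removed (0.043).

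**Figure D2:**
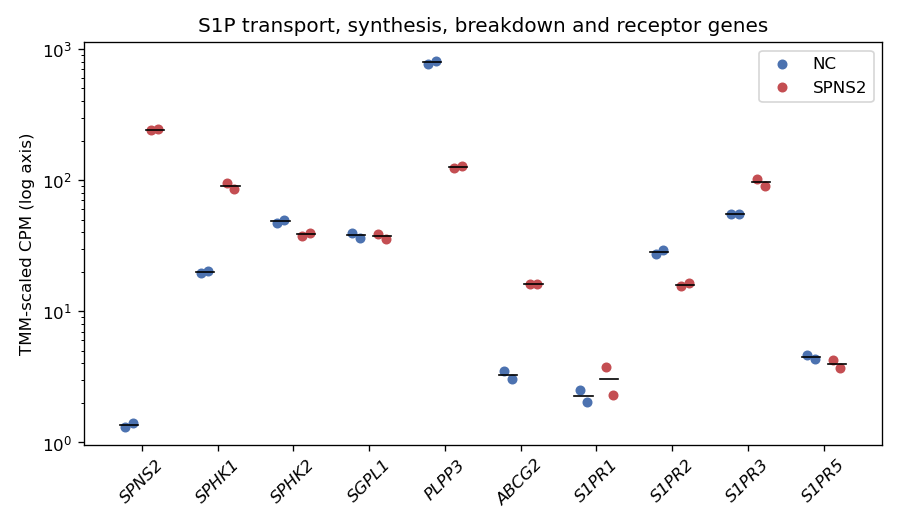
TMM-scaled CPM on a log axis for genes of S1P transport, synthesis, breakdown and reception, with each library as a point (NC blue, SPNS2 red) and the mean of each group as a black line. SPNS2, SPHK1, ABCG2 and S1PR3 lie higher in both SPNS2 libraries, PLPP3 and S1PR2 lie lower, and SGPL1 lies at 38 and 37.2 CPM.

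Of the 47 gene lists tested, camera with an estimated correlation called 0. That setting takes its degrees of freedom from the 4 libraries and could hardly call any list, so its adjusted p-values decide for or against none. With a preset correlation camera called 12 lists, with 9 higher and 3 lower in the SPNS2 cells. Cholesterol synthesis had the highest median of these lists, 0.72 on the log2 scale: 19 of 26 members rose, none fell and 7 were not called, with 20 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.658 with an estimated correlation). SREBF2, the transcription factor that drives the pathway, rose 2.1-fold from 121 ± 1.01 to 253 ± 5.11 CPM, and the enzymes LSS, ACAT2 and FDPS rose 2.74-, 2.03- and 1.99-fold. In the list of fatty acid synthesis and desaturation, 12 of 25 rose, 3 fell and 10 were not called, with 14 and 3 when adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.606 with an estimated correlation). Desaturase genes were among them: SCD rose from 282 ± 0.139 to 748 ± 95.2 CPM and SCD5 from 7.44 ± 0.944 to 34.9 ± 1.15 CPM, while the fatty acid synthase FASN rose 1.62-fold and the acyl-CoA synthetase ACSL5 2.77-fold.

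The lists of YAP and TAZ targets and of SRF-MRTF cytoskeletal genes were called higher. In the YAP-TAZ list, 14 of 25 members rose, 4 fell and 7 were not called, with 16 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.606 with an estimated correlation). CCN1, a secreted matricellular protein, rose 6.79-fold from 58.1 ± 0.12 to 395 ± 34.5 CPM, F3, tissue factor, rose 10.6-fold to 101 ± 5.89 CPM, and the receptor kinase AXL rose 2.19-fold to 1351 ± 29.6 CPM. IGFBP3 belongs to the same list and fell. In the SRF-MRTF list of cytoskeletal genes, 9 of 22 rose, 1 fell and 12 were not called, with 11 and 2 when adjusted over the list alone (camera adjusted p = 0.0074, adjusted p = 0.658 with an estimated correlation). The non-muscle myosin gene MYH9 rose 2.51-fold to 2241 ± 45.1 CPM, the actin crosslinker ACTN1 rose 1.8-fold, the focal adhesion gene ZYX 2.06-fold and the filamin FLNA 1.32-fold.

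Both cell cycle lists were called higher. In the list of DNA replication and S phase, 11 of 40 members rose, none fell and 29 were not called, with 12 higher when adjusted over the list alone (camera adjusted p = 0.00096, adjusted p = 0.658 with an estimated correlation). MCM7, part of the replicative helicase, rose 1.58-fold from 189 ± 0.0042 to 298 ± 16.5 CPM and the licensing factor CDC6 rose 1.59-fold. In the G2M and mitosis list, 15 of 40 rose, 1 fell and 24 were not called, with 17 and 1 when adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.658 with an estimated correlation). The phosphatases CDC25B and CDC25C rose 1.51- and 2.36-fold, the ubiquitin-conjugating enzyme UBE2C 1.51-fold and the kinetochore gene NUF2 1.82-fold.

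Ribosomal proteins showed the lowest p of all lists: 30 of 58 members rose, 1 fell and 27 were not called, with 37 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.658 with an estimated correlation). RPS14 rose 1.92-fold from 270 ± 0.424 to 518 ± 20.9 CPM, and RPL18, RPL37 and RPS23 rose 1.68-, 1.68- and 1.62-fold. RPS14, RPL37 and RPS23 lie on chromosome 5, whose arms had medians of 0.3 and 0.43 over all their tested genes. With the arm medians removed, 25 ribosomal protein genes were called higher and 0 lower, and the list was still called (camera adjusted p = 3.5e-07). In the list of nuclear genes of oxidative phosphorylation, 10 of 44 rose, none fell and 34 were not called, with 12 when adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.606 with an estimated correlation), among them UQCRC1 with a 1.52-fold rise. The mitochondrially encoded genes, a separate list, had 7 of 13 members lower, none higher and 6 not called, with 9 lower when adjusted over the list alone, and were not called as a list (camera adjusted p = 0.135). MT-CO1 fell 1.32-fold from 11990 ± 415 to 9087 ± 164 CPM and MT-CO3 fell 1.26-fold.

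The heat shock list was called higher and the list of the unfolded protein response lower. Of 20 heat shock genes, 9 rose, none fell and 11 were not called, with 13 higher when adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.606 with an estimated correlation). The chaperone HSP90AA1 rose 2.37-fold from 1658 ± 32.5 to 3931 ± 165 CPM, and HSPH1, HSPA4 and DNAJA1 rose 1.7-, 1.62- and 1.4-fold. Of 25 genes of the unfolded protein response, 2 rose, 14 fell and 9 were not called, with 2 and 15 when adjusted over the list alone (camera adjusted p = 0.0074, adjusted p = 0.658 with an estimated correlation). HYOU1, a chaperone of the endoplasmic reticulum, fell 2.22-fold from 816 ± 16.6 to 367 ± 45.4 CPM, HSP90B1 fell 1.58-fold to 1228 ± 19.6 CPM, and SEL1L and DNAJC10 fell 1.56- and 1.48-fold. HSPA4 lies on 5q and HYOU1 on 11q, arms with medians of 0.43 and -0.39 over all their tested genes. With the arm medians removed, the heat shock and unfolded protein response lists were still called (camera adjusted p = 0.00016 and 0.0083).

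The interferon list and the list of NF-kB targets and cytokines were called lower in the SPNS2 cells. Among 38 interferon-stimulated genes, 2 rose, 19 fell and 17 were not called, with 2 and 22 when adjusted over the list alone (camera adjusted p = 1.5e-05, adjusted p = 0.606 with an estimated correlation). RSAD2, an antiviral enzyme, fell 15.4-fold from 12.6 ± 1.44 to 0.813 ± 0.09 CPM, its neighbour on chromosome 2, CMPK2, fell 3.22-fold, and the oligoadenylate synthetases OAS1 and OAS3 fell 5.29- and 2.01-fold. In the list of NF-kB targets and cytokines, 3 of 28 rose, 13 fell and 12 were not called, with 3 and 15 when adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.658 with an estimated correlation, fry adjusted p = 0.0626). CXCL8, a chemokine for neutrophils, fell 3.87-fold from 343 ± 28.2 to 88.6 ± 14.6 CPM, the pentraxin PTX3 fell 2.68-fold from 1048 ± 44.6 CPM, and TNFAIP3, an inhibitor of NF-kB signalling, fell 1.66-fold. IL1B, interleukin 1 beta, went the other way and rose 14.5-fold from 2.66 ± 0.189 to 38.5 ± 0.782 CPM.

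**Figure D3:**
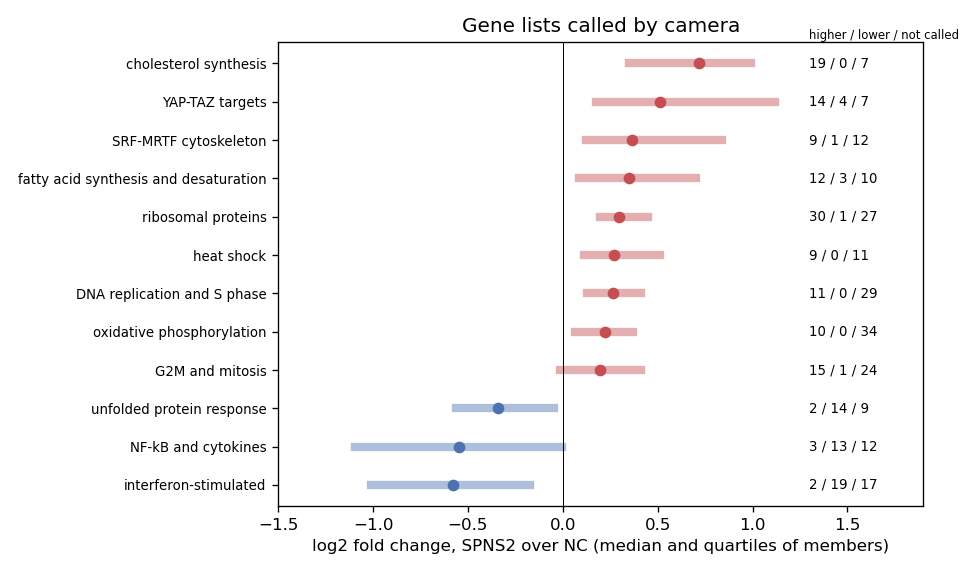
Median (points) and quartiles (bars) of the log2 fold changes of SPNS2 over NC, for the members of each of the 12 lists called by camera, with the numbers of members called higher, called lower and not called at the right. The medians run from -0.58 for interferon-stimulated genes to 0.72 for cholesterol synthesis.

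Genes of some chromosome arms were shifted together. On 5q, 239 of 701 tested genes rose and 30 fell, with a median log2 fold change of 0.43, and on 5p 46 of 150 rose and 10 fell, with a median of 0.3. On 11q, 26 of 630 rose and 173 fell (median -0.39), and on 4q 23 of 436 rose while 76.8% lay below the median of all tested genes (median -0.32), whereas 11p had a median of 0.15. Each pair of libraries gave the shift of 5q, with medians of 0.45 between the first and 0.4 between the second SPNS2 and NC libraries, against -0.0070 between the NC and -0.0062 between the SPNS2 libraries. The SD of the medians of the 42 arms was 0.18, and the highest in 10000 permutations of gene positions was 0.0847 (permutation p = 1e-04, the smallest they can give), across genes, which are not independent replicates. The largest shift of an arm from the median of all genes, that of 5q, was 0.441, and the highest in the permutations was 0.476 (permutation p = 3e-04). Both comparisons were made after the data were seen.

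**Figure D4:**
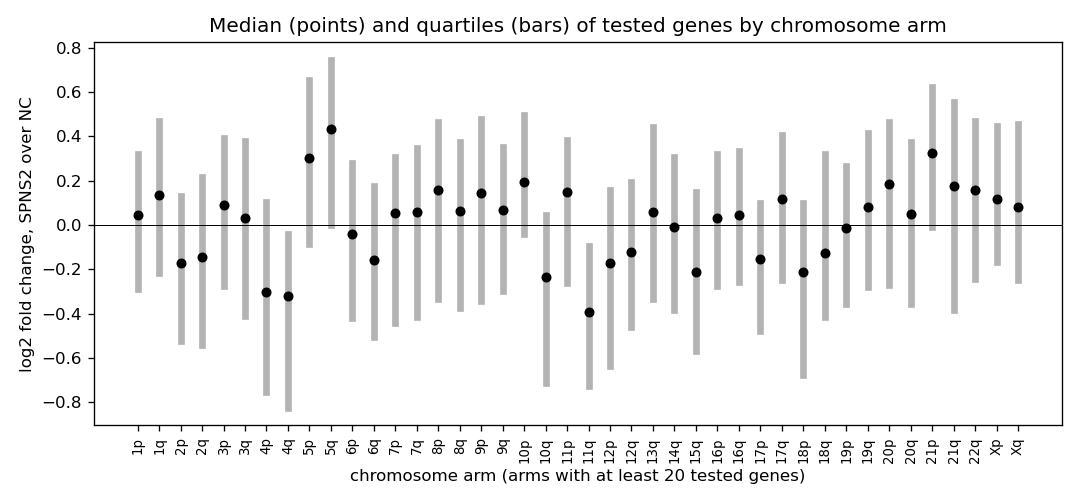
Median (points) and quartiles (bars) of the log2 fold changes of SPNS2 over NC for the tested genes of each chromosome arm with at least 20 of them. The medians of 5q (0.43) and 11q (-0.39) lie farthest from 0.

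Markers of other cell types gave no list call: camera called 0 of the 6 cell type lists tested, with 0 at an unadjusted p under 0.05, and the rotation test fry, which asks whether members move on balance one way, called the endothelial (adjusted p = 0.0238) and epithelial (adjusted p = 0.041) lists as moving. In the astrocyte list 1 of 12 members rose and 3 fell (camera adjusted p = 0.68): the glutamate transporter SLC1A3 rose 18.5-fold from 1.02 ± 0.143 to 19 ± 1.65 CPM, while the connexin GJA1 fell 2.73-fold and the clusterin gene CLU 3.63-fold. Of 8 neuronal genes 2 rose and 2 fell (camera adjusted p = 0.709), among them SYT1, which fell 6.21-fold from 15.9 ± 0.396 CPM. Of 7 endothelial genes 2 rose and 1 fell (camera adjusted p = 0.413), with TIE1 rising from 1.31 ± 0.346 to 23.3 ± 3.42 CPM. In each of the oligodendrocyte, microglia and macrophage, and epithelial lists 1 member fell and none rose (camera adjusted p = 0.324, 0.97 and 0.386). These calls (ERMN, CD68 and KRT14) and those of PECAM1, VWF and GAD1 in the endothelial and neuronal lists were each lost in at least 2 of the 4 fits without one library. The lymphocyte and erythroid lists had 2 and 0 tested genes and were not tested.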

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

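Every alternative was chosen before the data were examined except the removal of arm medians, which was chosen after seeing them. SPNS2 was called under each alternative run for single genes (glmTreat was run for the counts only), with log2 fold changes of 7.43 to 7.64. The 4171 calls (2161 higher, 2010 lower) stayed within 1.5 times under DESeq2 (5039), limma-voom (4248), the robust fit (4310), RLE (4142) and upper-quartile factors (4137), library totals (4141), no filter (3336), a mean of 1 CPM (3979) and arm medians removed (3278). Of the main calls 80% to 99.4% were kept under these planned ones and 71.1% with arm medians removed, and no kept call changed sign. Library totals moved the share of higher calls from 51.8% to 44.7% and the median of all genes to -0.06. Against a fold of 1.2, glmTreat called 2394 genes, 1204 higher and 1190 lower, since its threshold is stricter. Without one library in turn, 1712 to 2144 genes were called, 950 to 1093 higher, 762 to 1051 lower and 1061 to 1233 with at least a 2-fold change, with fewer samples to estimate the spread from, and the lone library of a group is assumed to vary like the others.

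The groups share only replicate numbers: deviations of same-numbered libraries had a correlation across genes of -0.08. With a replicate block, 1976 genes were called, 1039 higher, 937 lower and 1073 with at least a 2-fold change, a fit with fewer residual degrees of freedom, and the same 12 lists.

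The 12 list calls remained under each filter, library totals, each left-out library, the block and arm medians removed, with histones and HOX genes added at a mean of 1 CPM (14 lists) and histones without NC replicate 2 (13). With an estimated correlation 0 lists were called (1 at an unadjusted p under 0.05); fry called 24 directionally, 11 of the 12 among them (not NF-kB targets and cytokines, adjusted p = 0.0626), and 47 in its mixed form, which asks another question. Estimated correlations were -0.015 for interferon, -0.038 for YAP-TAZ, -0.0097 for fatty acid, -0.0047 for heat shock and 0.0028 for oxidative phosphorylation lists. All lie below the preset 0.01, which argues against correlation between members as the cause of the loss of these lists. In the other called lists it was higher, from 0.015 for SRF-MRTF to 0.33 for ribosomal proteins. The settings also differ in their degrees of freedom. With a preset correlation camera takes them from the number of genes, and with an estimated one from the 4 libraries. With so few libraries the estimated setting could hardly call any list, so its result decides for or against none. Other causes of the loss were not tested.

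Of up to 178 named genes, at least 149 kept direction and side of the threshold under each of these alternatives, the fewest without NC replicate 2. SGPL1, not called, ranged from -0.092 (without NC replicate 2) to 0.037 (without NC replicate 1) with one library left out and turned to 0.21 with arm medians removed, and SQSTM1, on 5q, turned from 0.43 to -0.00297 with arm medians removed. Lists that camera did not call turned direction as follows, with adjusted p-values, and the cause was not tested. By fry: Notch targets 0.0297, Wnt targets 0.048, angiogenesis factors 0.0314, potassium and calcium channels 0.0863 and HOX genes 0.214. Without a filter: S1P pathway 0.992, immediate early 0.992, Notch 0.864, microglia 0.848 and endothelial 0.992. With library totals: microglia 0.962. With the block: immediate early 0.842. With one library left out, the p-values of lists that turned in some of these fits ranged from 0.787 to 0.941 (S1P pathway), 0.771 to 0.967 (SPNS relatives), 0.858 to 0.955 (immediate early), 0.772 to 0.955 (Notch), 0.612 to 0.967 (mesenchymal glioblastoma) and 0.549 to 0.948 (microglia). With arm medians removed: SPNS relatives 0.778 and mesenchymal genes 0.893. Depth limits genes at a few counts, whose fitted folds are not sizes.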

Other observations

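The lists of this part and the rule that names their members were fixed before the data were examined, and the test of chromosome segments was set out before its result was seen; the tests of arms (a few genes, length and GC content, copies), of cells of another type, of overlapping genes and of counting error, the gene families and the even counts were chosen after the results were seen. Genes of the extracellular matrix changed in both directions. Of 35 collagens and crosslinking genes 9 rose and 10 fell (10 and 12 when adjusted over the list alone, camera adjusted p = 0.631), and COL5A1 and COL5A2, fibrillar collagens, fell 1.96- and 2.04-fold. Among 33 matrix proteases and inhibitors 13 rose and 9 fell (14 and 12 when adjusted over the list alone, camera adjusted p = 0.717): MMP16 rose 3.32-fold and ADAMTS1 fell 2.17-fold. Of 32 integrin and adhesion genes 14 rose and 8 fell (16 and 9 when adjusted over the list alone, camera adjusted p = 0.437), with ITGA3 rising 2.07-fold and ITGA8 and LAMA3 falling 11.1- and 5.54-fold. In the list of mesenchymal genes, SNAI2, a transcription factor of the epithelial-mesenchymal transition, rose 4.06-fold and the fibrillin FBN1 fell 2.38-fold, with 9 of 27 members higher and 8 lower (11 and 9 when adjusted over the list alone, camera adjusted p = 0.87).

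Targets of the antioxidant factor NRF2 were lower in number more often than higher, 10 against 2 of 27 (11 and 4 when adjusted over the list alone), without a list call (camera adjusted p = 0.15). SLC7A11, the cystine transporter, fell 4.69-fold from 684 ± 3.01 to 146 ± 21.8 CPM, AKR1C1 fell 3.45-fold and ABCC1 1.62-fold. In the ATF4 list 10 of 31 fell and 2 rose (11 and 4 when adjusted over the list alone, camera adjusted p = 0.0954), with SLC1A4 3.58-fold and ALDH1L2 2.96-fold lower. Of 12 proneural glioblastoma genes 5 rose and 2 fell (6 and 2 when adjusted over the list alone, camera adjusted p = 0.413): PDGFRA, the member with the smallest p, fell 2.79-fold, while NCAM1 rose 24.3-fold from 0.997 ± 0.443 to 24.3 ± 3.28 CPM and SOX11 rose 4.92-fold.

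The shift of whole arms was weighed on 5q, the arm with the highest median (0.43). A few strongly changed genes do not account for it, since the lower quartile of the arm lay 0.422 above that of all tested genes (bootstrap interval 0.34 to 0.475), nor does a trend with transcript length and GC content, after whose removal the median was 0.453. A different number of copies of the arm in the SPNS2 and the NC cultures is a candidate explanation that stays open: 75.3% of its genes lay above the median of all genes, between the bounds set for and against it. The introduced SPNS2 also stays open, since each group is 1 set of cultures and DNA was not measured, so the construct and the history of the cultures cannot be told apart.

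With thresholds chosen after seeing the data, 54 genes had a mean of at least 2 CPM in SPNS2 and under 0.25 CPM in both NC libraries, and 56 genes the reverse. Cells of another type mixed into one group would add genes in one direction, and 49.1% of these genes lay in the smaller direction. Such mixing alone would therefore not give both sets. The share only restates the 54 and 56 genes. Genes changed for other reasons could hide added ones, so mixing is not excluded. Shifts of whole segments may account for some of the genes of either set. The 50 nearest tested genes had a signed median of 0.0806 (bootstrap interval 0.03 to 0.155). That interval spans the bound of 0.1 set against this explanation and lies under the 0.3 set for it. The effect of SPNS2 itself stays open and untested. Such genes included EYA2 (9.61 CPM in NC and 0 in SPNS2), ELN (14.7 and 0.187 CPM) and LRRN1 (0 and 9.17 CPM), chosen after their values were seen.

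Within a group, genes with a mean above 5 CPM differed over 4-fold between the 2 replicates in 130 cases, 12 genes doing so in both groups, and 1 of these cases was a called gene. Counting error covered 0% of them. At this depth the thresholds on mean and ratio fix that outcome, so it follows from the selection and is not a separate test result. Of the 66 cases with a same-strand overlapping gene, summing both lowered the median absolute log2 ratio from 2.95 to 0.255, but summing with a more abundant gene, as in 63.6% of them, lowers a ratio in any case, so a stricter test was run in its place. By it, 40.9% (exact binomial interval 29% to 53.7%) had overlapping genes that differed the other way by 0.5 to 1.5 times as much, against at most 22.7% in 1000 draws of random partners, so reads divided differently between overlapping gene models may account for part of the cases, as at TXNDC5 (37.9 and 453 CPM in the SPNS2 libraries), where BLOC1S5-TXNDC5 had 416 and 0 CPM. The other 64 cases, such as AHNAK (111 and 3063 CPM) and MYC (52.5 and 9.29 CPM in SPNS2, 5.68 and 34.4 CPM in NC), have no such partner in the annotation used and stay open. That annotation matched 17382 of the 17853 tested genes. A gene without a position in it was also counted as having no partner, so overlaps of such genes could not be seen. TXNDC5, AHNAK and MYC were chosen after their values were seen, and no biological explanation was tested.

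Camera over 275 families of genes that share the letters of their symbol called 1, RPL, with 28 of 134 members higher, 0 lower and a median log2 fold change of 0.28 (adjusted p = 0.0059, adjusted p = 0.945 with an estimated correlation). RPL shares members such as RPL18 and RPL37 with the ribosomal protein list, so it is not a separate finding. The RPS family, with 18 of 79 members higher and 3 lower, was not called (camera adjusted p = 0.485). Even values made up 52.6% to 53.5% of the counts from 1 to 20 in the 4 libraries.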
